A study of Epinephelus fuscoguttatus x Epinephelus lanceolatus with 9 samples.

How the data were processed

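Intestine of pearl gentian grouper, a farmed hybrid of Epinephelus fuscoguttatus and Epinephelus lanceolatus, was profiled by RNA sequencing in 9 libraries. The labels place 3 libraries in each of 3 groups called FM, SBM and Drug. In fish nutrition FM and SBM are common short forms of fish meal and soybean meal, but the labels do not spell them out. The series title names Lithospermum erythrorhizon, a herb used in Chinese medicine, and the labels give no dose, duration or base diet for the Drug group. They also give no time of sampling and no gut segment. Nothing in the labels says that the libraries of a group came from separate fish, so p-values measure only the spread between these libraries, which may be technical.

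Per the labels' protocols, total RNA was extracted with TRIzol and libraries were built with the VAHTS Universal V6 kit. The submitters' processing notes name fastp, HISAT2, HTSeq, DESeq2 and R 3.2.0, without their roles. The same notes name the build mm10, a mouse assembly. The gene symbols in the deposited tables are fish symbols, so the genome the reads were aligned to is not given in the sources used here. Reads of a hybrid carry alleles of both parent species, and genes on which those alleles differ from the reference can be undercounted. No genome or annotation was used here, and genes are named by symbol with no coordinates.

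The deposited counts were whole-number read counts per gene, not normalized, for 22344 genes in 9 libraries. In all 9 cases the deposited file of a single library held the same values as its column of the series table. Of the 22344 genes, 8101 carried only a bare LOC number with no name, and these held 27.7% of all counts. The deposited FPKM table was computed by the authors from those counts: in each of the 15780 genes with at least 10 counts in every library, FPKM times library total over count was equal in all libraries within a relative tolerance of 1e-06. FPKM is therefore scaled by the total count alone. Fish genomes hold many duplicated genes (symbols ending in a and b), and near-identical copies can share reads, so single members of such pairs are uncertain. Counting is not stated to use strand, so antisense partners were not told apart.

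Total counts ranged from 32.9 to 35.5 M counts per library, so counting error was small beside the spread between libraries for all but genes of low count. Replicates were compared before they were averaged. Within a group the smallest chi-square per degree of freedom between 2 libraries was 56.1, far above sampling noise, so no library was treated as a copy of another.

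Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, filterByExpr defaults, TMM factors, robust fit) on the counts as deposited. All 9 libraries entered 1 model with the 3 groups and no covariate, which left 6 residual degrees of freedom and 17731 tested genes. Tests were two-sided with Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 passed. CPM values are TMM-scaled, given as mean ± SD over n = 3 libraries. Group means use the total of the tested genes, while values of marker genes in single libraries use the total of all genes and are therefore slightly lower in FM replicate 3. Standard errors of log2 fold changes were derived as the absolute log2 fold change over the square root of the F statistic.

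A set of 41 gene lists (pathways, cell-type markers and signs of RNA quality) was fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists were matched on symbol, so genes with a bare LOC number belong to none. The 40 lists with at least 5 tested members were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with a correlation estimated per list and fry's directional test were run beside it. Named genes are the 8 largest positive and the 8 largest negative log2 fold changes of each comparison. These were taken among genes past the threshold that had a mean of at least 5 CPM in 1 group, values of the 2 groups that did not overlap, and a name other than a LOC number. In addition, up to 4 members with the smallest p could be named for each list described, and up to 2 members with the highest mean CPM for marker lists of other cell types.

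The gene test and the list test were checked on simulated counts drawn from the real gene means, library sizes and dispersions of the 17731 genes. In each simulated comparison 100 genes changed 2-fold and 100 changed 4-fold. For SBM vs FM, 3 of the 2-fold and 59 of the 4-fold changes were recovered with 3 false calls among 65. For Drug vs SBM the numbers were 8 and 68 with 4 false calls among 80, and for Drug vs FM 4 and 75 with 0 false calls among 79. Changes of 2-fold were thus mostly out of reach at this sample size. A simulated 2-fold rise of the sterol biosynthesis list passed the list test in all 3 comparisons, and of the other lists, to which no change was given, 0, 0 and 1 passed. The simulated genes were drawn independently of each other, while the sterol list had an estimated correlation of 0.64 in SBM vs FM. The check therefore does not give the error rate of the list test for lists whose genes vary together.

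Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, no filter beyond 1 count, a stricter filter of 10 CPM in 3 libraries, fits on only the 2 groups compared, the replicate number of the titles as a block, and an added bound of 1 on the absolute log2 fold change. Further alternatives were limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), and each library left out in turn. Fitting on FPKM shifted the median log2 fold change of all genes in SBM vs FM from 0.01 to -0.10 and -0.17. Further alternatives were chosen after seeing the data: leaving out FM replicate 3 and SBM replicate 2 together, removing genes over 10-fold above every other library in FM replicate 3, and adding a score of lysosome-rich enterocyte genes per library as a covariate.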

Results

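RNA sequencing of the intestine of pearl gentian grouper gave 9 libraries, 3 each from the FM, SBM and Drug groups. The total count was 33.9, 33.98 and 34.6 M in FM, 32.9, 35.5 and 35.3 M in SBM, and 35.1, 34.3 and 34.1 M in Drug, in order of replicate number. Between 20150 and 20588 of the 22344 genes had a count in each library, and the 10 most abundant genes held 8.43% to 10.5% of the counts. Mitochondrially encoded genes held 2.62% of counts in SBM replicate 1 and 4.66% in FM replicate 3, the lowest and highest values.

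The SBM libraries were not all alike. On the log2(CPM + 1) scale SBM replicate 2 correlated at 0.937 with SBM replicate 1 and at 0.976 with SBM replicate 3. Its correlation with FM replicates 1 and 2 was 0.960 and 0.961. The same values were 0.958 and 0.932 for SBM replicate 1 and 0.965 and 0.948 for SBM replicate 3. SBM replicates 1 and 3 correlated at 0.970, so these values do not single out SBM replicate 2. FM replicate 3 stood apart in its content, with abundant transcripts of blood proteins that hepatocytes secrete. Hemopexin (hpxb) was at 6306 CPM there and at 0.246 and 0.0264 CPM in FM replicates 1 and 2, and transferrin (tfa) was at 2947 CPM against 5.53 and 11.3 CPM. Of the 16 genes of the hepatocyte list in the table, 15 stood over 10-fold above the highest of the other 8 libraries in FM replicate 3, a bound chosen after seeing the data. A total of 252 genes met that bound with at least 5 CPM, and they held 9.18% of the counts of this library. Pancreatic enzyme transcripts, a list with too few tested members for a test, also varied within groups: carboxypeptidase cpa5 was at 685 CPM in SBM replicate 1 and 135 CPM in SBM replicate 3, and at 484 CPM in FM replicate 3 and 50.8 CPM in FM replicate 2.

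**Figure D1:**
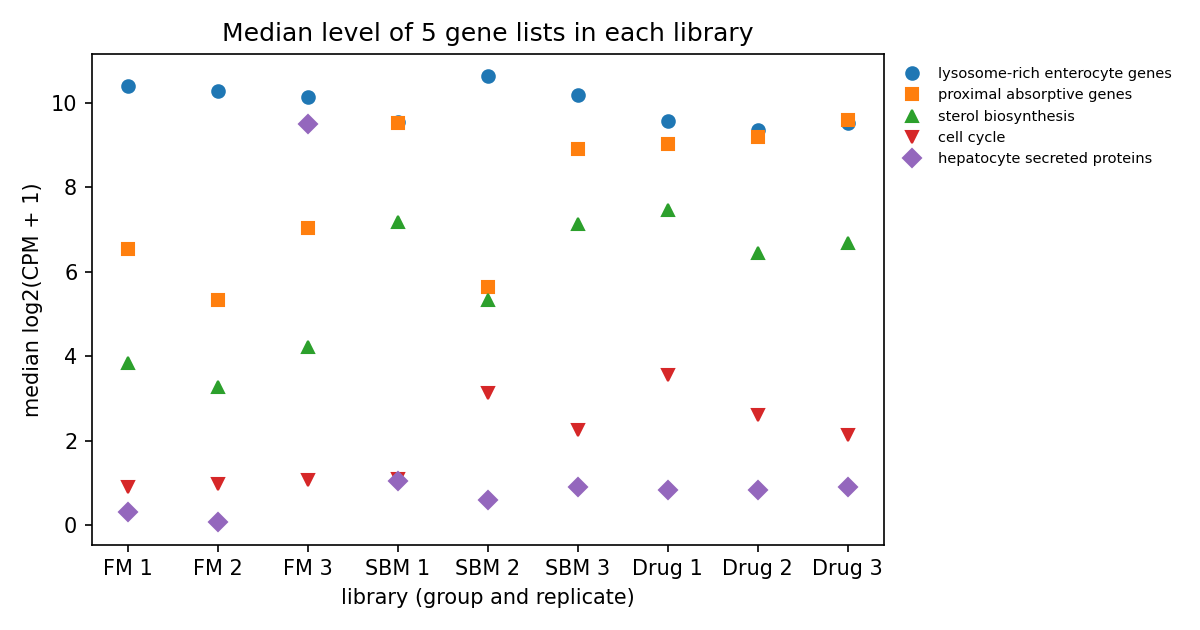
Median log2(CPM + 1) of 5 gene lists in each of the 9 libraries, 1 symbol per list and library, with no error bars. The hepatocyte list lies at 9.50 in FM replicate 3 and at most 1.05 in every other library, and the sterol biosynthesis list lies at 4.23 or below in FM and at 5.33 or above in SBM and Drug.

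The first comparison asked how the intestine of the SBM group differed from that of the FM group. Genes of sterol synthesis were far higher in SBM. Squalene epoxidase (sqlea) rose from 1.64 ± 0.991 CPM in FM to 211 ± 117 CPM in SBM (SD, n = 3; log2 fold change 7.01, SE 0.90, adjusted p = 0.0298). Methylsterol monooxygenase (msmo1) rose from 15.6 ± 7.8 to 541 ± 241 CPM (log2 fold change 5.12, SE 0.65, adjusted p = 0.0283). The sterol regulator srebf2 rose 3.92-fold and erg28, a scaffold of the sterol demethylation complex, rose 7.67-fold. The sterol exporter abcg5 fell from 102 ± 10.3 to 36.8 ± 9.58 CPM.

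Of the 25 tested genes of the sterol biosynthesis list, 3 rose over all genes tested, 22 did not pass, and none fell. That count was 0 on the 2 groups alone and without any one of FM replicates 1, 2 and 3, SBM replicate 3 and Drug replicates 2 and 3. It was 12 without SBM replicate 2, 11 without FM replicate 3 and SBM replicate 2, 6 with the stricter filter and 19 with DESeq2. Adjusted over the list alone, 20 rose. All 25 had a positive log2 fold change, with a median of 2.18, and the list passed camera at an adjusted p of 2.09e-24. With an estimated correlation its adjusted p = 0.539. Median sterol levels in SBM were highest in replicates 1 and 3, at 7.17 and 7.14 on the log2(CPM + 1) scale, and 5.33 in replicate 2, against 3.27 to 4.23 in FM.

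Other genes with large rises in SBM were greb1, an estrogen-regulated growth gene, which went from 1.58 ± 0.261 to 17.95 ± 5.8 CPM (log2 fold change 3.50, SE 0.27, adjusted p = 0.00276), and vwa11, which rose 25.3-fold. The stress-response gene tp53inp1 rose 9.61-fold, the epithelial transcription factor klf4 rose 6.96-fold, and the formin-domain gene fhdc2 rose 4.62-fold. The genes that fell most were csf3a, a granulocyte growth factor, from 8.49 ± 2.18 to 1.57 ± 0.398 CPM (log2 fold change -2.43, SE 0.34, adjusted p = 0.0298), and the Ras-family gene diras1b, which fell 3.12-fold. Lesser falls were seen in the polarity gene crb3b (2.97-fold), the mitochondrial fission gene mtfp1 (2.46-fold), b3gnt5b (2.29-fold), uspl1 (2.25-fold) and the Hippo pathway gene wwc1 (2.21-fold).

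Genes of fat burning and respiration lay higher in SBM as well. Of 33 tested genes of mitochondrial and peroxisomal fatty acid oxidation, 3 rose and none fell. These were the acyl-CoA dehydrogenase acadvl, 2.59-fold, and the carnitine palmitoyltransferases cpt1ab, 2.31-fold, and cpt1b, 5.52-fold, and 30 did not pass. The count of 3 was 0 on the 2 groups alone and without any one of FM replicates 1 and 2, SBM replicate 3 and Drug replicates 2 and 3, and 1 without FM replicate 3, without Drug replicate 1 and in both fits to FPKM. It was 5 without FM replicate 3 and SBM replicate 2 and without liver-restricted genes, 7 without SBM replicate 1, 8 with the score of lysosome-rich enterocyte genes as a covariate and 13 with DESeq2. Adjusted over the list alone, 14 rose. The list had an adjusted p of 5.93e-08 by camera, and adjusted p = 0.727 with an estimated correlation. None of 70 oxidative phosphorylation genes passed with edgeR, against 14 with DESeq2, 3 without SBM replicate 1, 4 with the covariate and 2 with the stricter filter. Positive log2 fold changes were seen in 65 (median 0.45), and 19 rose when adjusted over the list alone. That list passed camera at 1.14e-08, with adjusted p = 0.752 under an estimated correlation. The median of the respiration genes was 0.26 and 0.27 in the fits to log2(FPKM + 1) and log2(FPKM + 0.1). Its member with the smallest p, atp5f1b, was at 1181 CPM in SBM and 725 CPM in FM (adjusted p = 0.0539).

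None of 53 cell cycle genes passed over all genes tested with edgeR, against 27 with DESeq2, 13 without SBM replicate 1 and 23 with the score of lysosome-rich enterocyte genes as a covariate. In 51 of them the log2 fold change was positive (median 1.97), and 35 rose when adjusted over the list alone. The list passed camera at 7.98e-17, with adjusted p = 0.752 under an estimated correlation. The median was 1.17 without SBM replicate 2, 1.23 without FM replicate 3 and SBM replicate 2, 0.79 with the stricter filter, and 0.51 and 1.03 in the fits to log2(FPKM + 1) and log2(FPKM + 0.1). The proliferation marker mki67 was at 39.8 ± 5.82 CPM in SBM and 19.7 ± 4.14 CPM in FM (adjusted p = 0.0929). The cell cycle median of SBM replicate 1, 1.10 on the log2(CPM + 1) scale, was close to the 0.91 to 1.08 of FM, while replicates 2 and 3 were at 3.13 and 2.26.

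Single genes passed in other lists. In lipid absorption apoea rose 2.40-fold and the other 20 genes did not pass (camera adjusted p of 7.68e-05, and adjusted p = 0.752 with an estimated correlation). The claudin cldn15a rose 4.08-fold and the other 18 genes of the tight junction list did not pass (0.0138 by camera, and adjusted p = 0.539 with an estimated correlation). By fry the tight junction list had an adjusted p of 0.0459. Calsequestrin (casq2) rose 2.73-fold and the other 17 smooth muscle genes did not pass (5.03e-05 by camera, and adjusted p = 0.752 with an estimated correlation). In the inflammatory cytokine list csf3a fell and the other 21 genes did not pass (0.0107 by camera, and adjusted p = 0.752 with an estimated correlation). Over the alternatives the adjusted p ranged from 3.54e-17 to 0.0769 (without SBM replicate 1) for lipid absorption and from 6.34e-08 to 0.228 (without FM replicate 3 and SBM replicate 2) for smooth muscle. It ranged from 0.00793 to 0.0827 for tight junctions, with 0.0603 without FM replicate 3 and 0.05995 with the stricter filter, and from 0.00214 to 0.198 (stricter filter) for inflammatory cytokines, with 0.0769 without SBM replicate 1 and 0.0817 with the score of lysosome-rich enterocyte genes as a covariate. With that covariate the lipid absorption median was 0.44, against 0.94 without it. The glutathione genes gsr and mgst3a rose 1.84-fold and 2.04-fold, and nfkbiz, a regulator of NF-kappaB, fell 2.13-fold, in lists that did not pass. The rise of klf4 counts in the goblet cell and immediate early lists, which did not pass either. No gene named in this paragraph passed on the 2 groups alone or without any one of FM replicates 1, 2 and 3, SBM replicate 3 and Drug replicates 1, 2 and 3. The lipid absorption genes past the threshold numbered 7 without SBM replicate 2 and with DESeq2, 8 without FM replicate 3 and SBM replicate 2, and 3 with the covariate.

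In the lists of brush border digestion, enteroendocrine cells, fibroblasts and matrix, ion and water transport, and enteric neurons no gene passed with edgeR, yet each list passed camera upwards, with adjusted p between 0.00278 and 0.0408. The list of B and plasma cells passed downwards at 0.0107, also with no gene past the threshold. Without SBM replicate 2, 1 brush border, 2 ion transport and 2 enteroendocrine genes rose and 1 B cell gene fell, 1 ion transport gene rose without Drug replicate 1, and DESeq2 called 3, 4, 2 and 1 genes of these lists and 4 of the matrix list. With an estimated correlation their adjusted p lay between 0.561 and 0.771. Without SBM replicate 1 the adjusted p was 0.190 for brush border, 0.340 for enteroendocrine cells, 0.0769 for ion and water transport, 0.321 for enteric neurons and 0.190 for B and plasma cells. It was 0.117 for enteroendocrine cells and 0.774 for enteric neurons without FM replicate 3, 0.0895 for fibroblasts and 0.0664 for enteric neurons without SBM replicate 2, and 0.0698 for B and plasma cells without FM replicate 2. With the score of lysosome-rich enterocyte genes as a covariate it was 0.130 for brush border, 0.126 for enteroendocrine cells, 0.0817 for ion and water transport and for enteric neurons, and 0.0893 for B and plasma cells. Enteric neurons were at 0.0582 without a filter, as was ion and water transport, at 0.0592 on the 2 groups alone and at 0.0564 without liver-restricted genes. Enteroendocrine cells were at 0.0529 with the stricter filter, and B and plasma cells at 0.0659 and 0.0868 in the fits to log2(FPKM + 1) and log2(FPKM + 0.1). Without FM replicate 3 and SBM replicate 2 enteric neurons were at 0.770. The hepatocyte list passed downwards at 0.0271 (adjusted p = 0.779 with an estimated correlation). Most of its members were abundant in FM replicate 3 and scarce in the other libraries. Without FM replicate 3 this list passed in the opposite direction, at 2.00e-11 with 1 gene higher, and without SBM replicate 2 as well at 6.90e-10. Its adjusted p was 0.114 without SBM replicate 1, 0.0870 without SBM replicate 2, 0.0715 on the 2 groups alone, and 0.257 and 0.452 in the fits to log2(FPKM + 1) and log2(FPKM + 0.1).

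In total 105 of 17731 genes passed in SBM vs FM with edgeR, 79 higher and 26 lower, and 40 of them carried only a LOC number. Groups did not overlap in 22.8% of genes, against 10% by chance. DESeq2 called 1597 genes, the fit on the 2 groups alone called 0 (with 2769 at an unadjusted p under 0.05), and fits to log2(FPKM + 1) and log2(FPKM + 0.1) called 22 higher and 27 lower, and 35 higher and 34 lower. Without FM replicates 1, 2 and 3 the counts were 2, 2 and 23, without SBM replicates 1, 2 and 3 they were 424, 303 and 2, and without Drug replicates 1, 2 and 3 they were 31, 2 and 2. Leaving out FM replicate 3 and SBM replicate 2 together gave 330 genes, 74 of them among the 105. Of the 23 genes without FM replicate 3 alone, 10 were among the 105.

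**Figure D2:**
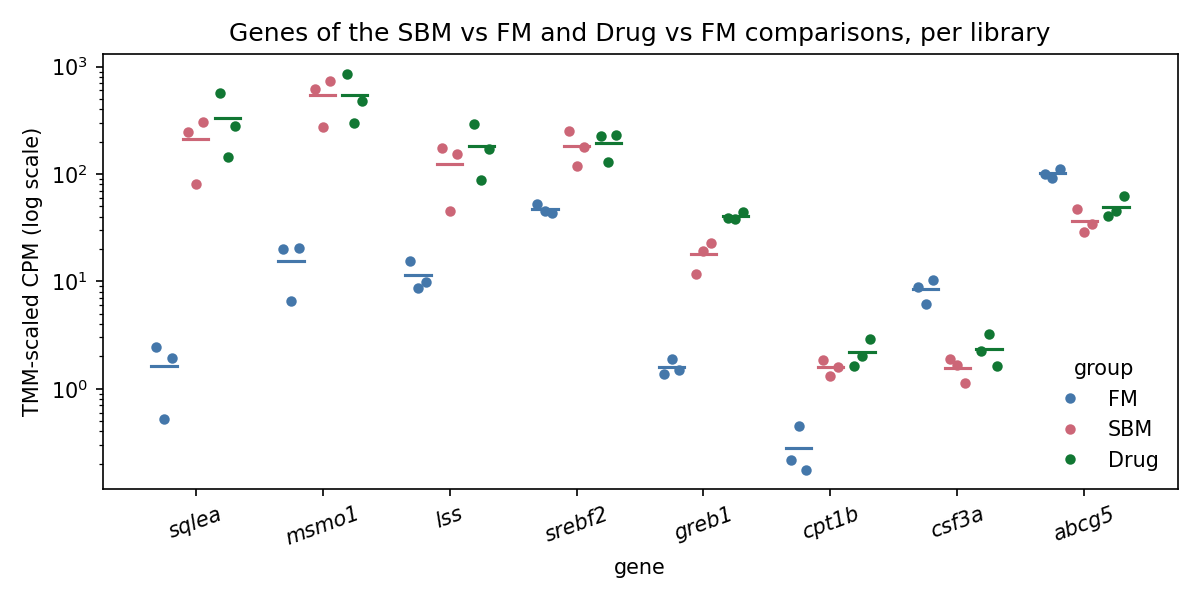
TMM-scaled CPM (log axis) of 8 genes in each library, with FM, SBM and Drug as separate colours, points for the 3 libraries and a bar for their mean. The FM libraries lie below the SBM and Drug libraries for sqlea, msmo1, lss, srebf2, greb1 and cpt1b, and above them for csf3a and abcg5.

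The second comparison asked what set the Drug group apart from the SBM group. Few genes passed, and all were lower in Drug. The kinase mknk2b, which phosphorylates the translation factor eIF4E, fell from 750 ± 116 CPM in SBM to 98.7 ± 45.7 CPM in Drug (SD, n = 3; log2 fold change -2.92, SE 0.35, adjusted p = 0.0426). The Notch target hey1 fell 3.95-fold, from 9.16 ± 1.55 to 2.32 ± 0.273 CPM. The oxidative stress growth inhibitor osgn1 fell 3.77-fold, from 106 ± 14.2 to 28.1 ± 4.89 CPM. The Hippo pathway effector yap1 fell 2.77-fold, from 28.3 ± 4.08 to 10.2 ± 0.83 CPM, and pnrc2, an mRNA decay factor, fell 2.60-fold. The remaining calls were LOC125897815 and LOC125900504, which have no name in the deposited tables, and all 7 calls had an adjusted p of 0.0426.

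**Figure D3:**
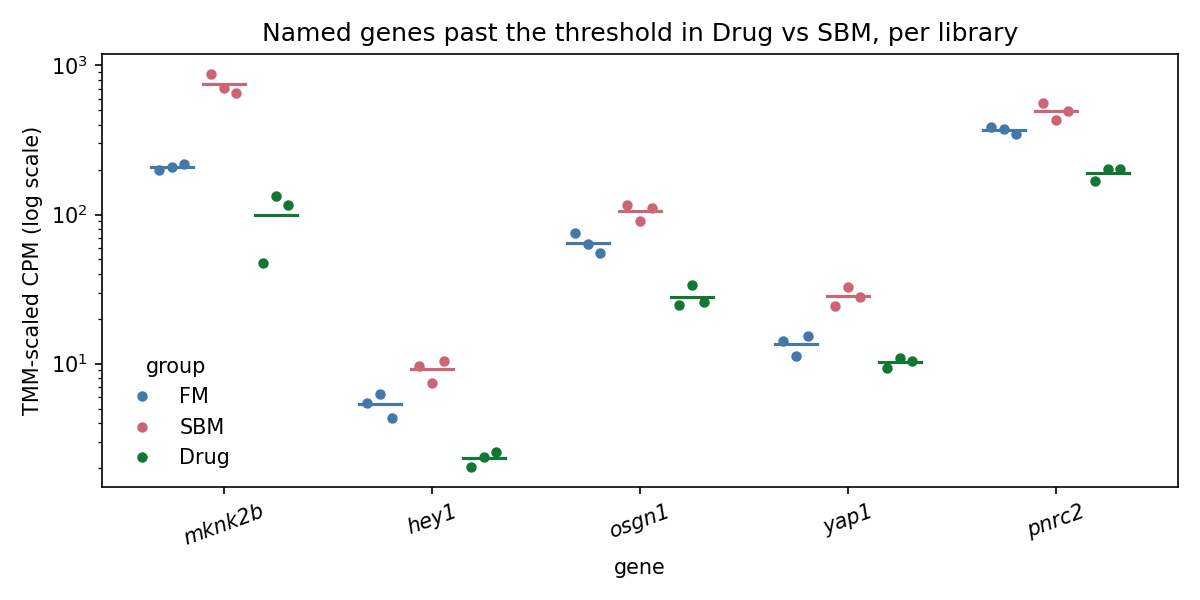
TMM-scaled CPM (log axis) of the 5 named genes past the threshold in Drug vs SBM, with points for the 3 libraries of each group and a bar for their mean. Each Drug library lies below each SBM library in all 5 genes.

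No member of a list past the threshold passed singly over all genes tested with edgeR in this comparison, while DESeq2 called 4 clock, 3 cell cycle, 2 tight junction, 5 immediate early and 2 lipid absorption genes. With the score of lysosome-rich enterocyte genes as a covariate 2 clock, 1 cell cycle and 2 immediate early genes passed. The circadian clock list lay lower in Drug, with 25 of 31 log2 fold changes negative (median -0.55), an adjusted p of 3.10e-07 by camera and adjusted p = 0.597 with an estimated correlation. Adjusted over the list alone, 4 of its genes fell, and the median was -0.32 with the score of lysosome-rich enterocyte genes as a covariate and -0.25 in the fit to log2(FPKM + 1). The clock repressor bhlhe40 was at 23.95 ± 4.25 CPM in Drug and 64.4 ± 8.53 CPM in SBM (adjusted p = 0.0776), and nfil3 was at 6.50 and 14.5 CPM (adjusted p = 0.158). The labels give no time of sampling, so a difference in time of day between these libraries cannot be told apart from the group. The cell cycle list lay higher in Drug, with 52 of 53 log2 fold changes positive (median 0.70), an adjusted p of 1.41e-08 by camera and adjusted p = 0.988 with an estimated correlation. Its replication genes mcm5 and mcm6 were at 43.0 and 42.0 CPM in Drug and 21.0 and 18.8 CPM in SBM (adjusted p = 0.196 and 0.206). The cell cycle median was 0.30 without SBM replicate 1 (adjusted p of 0.0518), 0.08 without Drug replicate 1, 1.32 without SBM replicate 2, 1.30 without FM replicate 3 and SBM replicate 2, 1.88 with the covariate and 0.46 in the fit to log2(FPKM + 1).

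The tight junction list lay lower in Drug, with a median log2 fold change of -0.35 and an adjusted p of 0.00300 by camera, and 2 genes fell when adjusted over the list alone. Its adjusted p = 0.415 with an estimated correlation, and fry gave an adjusted p of 0.0306. The median was -0.21 in the fit to log2(FPKM + 1). The claudins cldn5a and cldn23l were at 5.61 and 9.22 CPM in Drug and 12.3 and 24.8 CPM in SBM (adjusted p = 0.174 and 0.203). Immediate early genes had a median log2 fold change of -0.85 (camera adjusted p of 0.00772, and adjusted p = 0.988 with an estimated correlation). Among them fosab was at 520 CPM in SBM replicate 1, 64.0 CPM in replicate 2 and 148 CPM in replicate 3, against 47.4 ± 22.9 CPM in Drug, and dusp1 was at 593 CPM in SBM replicate 1 against 108 ± 33.3 CPM in Drug. The median of this list was -0.20 without SBM replicate 1, -1.34 with the covariate, and -0.37 and -0.45 in the fits to log2(FPKM + 1) and log2(FPKM + 0.1). Its adjusted p was 0.583 without SBM replicate 1, 0.0789 without Drug replicate 1 and 0.0969 without Drug replicate 3.

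Lipid absorption genes lay higher in Drug (median 0.50, camera adjusted p of 0.00332, and adjusted p = 0.988 with an estimated correlation). The intestinal fatty acid binding protein fabp2 was at 5986 ± 778 CPM in Drug and 2087 ± 1159 CPM in SBM (adjusted p = 0.240). The lipid absorption median was 0.95 without SBM replicate 1 and 0.20 without SBM replicate 2. The adjusted p was 0.468 without SBM replicate 2 and 0.192 without FM replicate 3 and SBM replicate 2, and with the score of lysosome-rich enterocyte genes as a covariate the median was -0.10 and the adjusted p 0.794. Ribosomal protein genes and smooth muscle genes lay lower (medians -0.25 and -0.52), and mitochondrially encoded genes lay higher (median 0.36). These 3 lists passed camera at 9.30e-05, 0.00177 and 0.00679, each with adjusted p = 0.988 under an estimated correlation. The adjusted p was 0.264 for mitochondrially encoded genes without SBM replicate 1, the library with the lowest share of these genes, and 0.0731 for smooth muscle genes without SBM replicate 2 (0.0845 with the covariate), with medians of -0.26 and -0.27. For ribosomal protein genes the median was -0.14 in both fits to FPKM. The sterol biosynthesis list did not pass (median 0.45, adjusted p of 0.0976), with a range of 0.000174 to 0.998 over 20 alternatives, 4 of which passed, and a median of 0.08 with the covariate.

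Altogether 7 of 17731 genes passed in Drug vs SBM with edgeR, none higher and 7 lower, while 2327 had an unadjusted p under 0.05. DESeq2 called 614 genes, 202 higher and 412 lower. The calls were lost with upper-quartile factors, with the 2 groups alone and without any one of FM replicates 1, 2 and 3, SBM replicates 2 and 3 and Drug replicates 2 and 3, which each gave 0 genes, and 1 gene was left without Drug replicate 1 and 36 without SBM replicate 1. Leaving out FM replicate 3 and SBM replicate 2 together gave 0 genes. With the replicate number as a block 1 gene passed, which was not among the 7, so all 7 calls were lost.

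A linked question was whether genes that differed between SBM and FM moved back in Drug. Only yap1 passed in both tests with opposite signs, rising 1.06 on the log2 scale in SBM over FM and falling in Drug, where it was at 10.2 CPM against 13.6 ± 2.1 CPM in FM. Independent lists of these sizes would share 0.0312 genes, and 20 simulations of unchanged groups with shared SBM libraries gave at most 0. No gene was given a change in these simulations, so an overlap near 0 was set in advance and decides nothing. Of the 105 genes of SBM vs FM, 71 had the opposite sign in Drug vs SBM and 34 the same sign. Genes picked for a difference in the shared SBM libraries lean to opposite signs by chance, so this count alone decides nothing. The log2 fold changes of the 2 comparisons had a covariance of -0.0803 across genes, against -0.114 in the simulations, and 60.1% of genes had opposite signs against 66.7% in the simulations. Across genes, opposite changes were thus weaker and fewer than in the simulations, so these 2 measures show no general move back in Drug. The simulations drew the libraries independently, while deviations from group means correlated at 0.05 to 0.37 between same-numbered libraries. The 2 measures therefore do not exclude a general move back. Tight junction and smooth muscle lists passed camera upwards in SBM vs FM (0.0138 and 5.03e-05) and downwards in Drug vs SBM (0.00300 and 0.00177). Their adjusted p in Drug vs FM was 0.894 and 0.366. Cell cycle and lipid absorption lists passed upwards in both SBM comparisons. Under an estimated correlation none of these passed, while fry passed tight junctions in both (0.0459 and 0.0306). The 3 SBM libraries cannot be split into parts of at least 2. The opposite list changes and the overlap in yap1 may therefore come in part from the shared libraries. The count of genes past both tests with opposite signs was 0 with upper-quartile factors, on the 2 groups alone and in both limma-trend fits. It was also 0 without any one of Drug replicates 2 and 3, FM replicates 1, 2 and 3 and SBM replicates 2 and 3. It was 9 without SBM replicate 1 and 150 with DESeq2. With the replicate number as a block it was 1, and that gene was not yap1. The fall of yap1 in Drug vs SBM itself passed in 7 of 21 alternatives.

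The third comparison set the Drug group against FM. Sterol genes again lay far higher. The sterol enzymes sqlea, msmo1 and lss, the last a lanosterol synthase, rose 202-fold, 34.98-fold and 16.1-fold. For lss the level was 183 ± 102 CPM in Drug and 11.3 ± 3.66 CPM in FM (SD, n = 3; log2 fold change 4.01, SE 0.62, adjusted p = 0.0182). Of 25 tested sterol genes 12 rose, 13 did not pass and none fell, and 22 rose when adjusted over the list alone. The count of 12 was 0 without FM replicate 2, 3 without FM replicate 1, 2 without Drug replicate 1 or 3, 20 with DESeq2 and 1 with the score of lysosome-rich enterocyte genes as a covariate. The median log2 fold change was 2.68 (camera adjusted p of 7.92e-27, and adjusted p = 0.561 with an estimated correlation).

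The cell cycle list lay higher too, with 13 of 53 genes past the threshold upwards, 50 when adjusted over the list alone, and none past it downwards. The replication licensing genes mcm4, mcm5 and mcm6 rose 3.28-fold, 3.83-fold and 3.93-fold, and mki67 rose from 19.7 ± 4.14 to 58.8 ± 18.8 CPM (log2 fold change 1.58, SE 0.26, adjusted p = 0.0183). The list passed camera at 1.57e-32, with adjusted p = 0.561 under an estimated correlation. Its median log2 fold change was 2.65, with 4.26 under the lysosome-rich enterocyte score as a covariate, 1.73 with the stricter filter and 1.07 in the fit to log2(FPKM + 1). The count of 13 was 0 without any one of Drug replicates 1 and 3 and FM replicate 2, 2 without FM replicate 1, 4 without Drug replicate 2, 5 without FM replicate 3 and 7 without SBM replicate 3 and in both fits to FPKM. It was 40 without SBM replicate 1, 31 without SBM replicate 2, 40 with the covariate, 38 on the 2 groups alone and 48 with DESeq2.

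Lipid absorption and fat oxidation genes were higher in Drug. In lipid absorption 5 of 21 genes rose and 16 did not pass, and 11 rose when adjusted over the list alone. The count of 5 was 0 without FM replicate 2, 1 without any one of FM replicate 1 and Drug replicates 1 and 3, and 2 without Drug replicate 2, without SBM replicate 3 and without a filter. It was 11 without SBM replicate 1 or 2, 13 without FM replicate 3 and SBM replicate 2, 12 on the 2 groups alone and 13 with DESeq2. Among them fabp2 went from 653 ± 225 CPM in FM to 5986 ± 778 CPM in Drug, apoea rose 3.44-fold, the acyltransferase mogat2 rose 4.95-fold and the lipid droplet protein plin3 rose 3.46-fold. The list passed camera at 9.86e-10, with adjusted p = 0.590 under an estimated correlation. A score of 10 genes of lysosome-rich enterocytes, cells that take up and digest protein, was 0.49, 0.50 and 0.26 in FM, -0.68, 0.77 and 0.16 in SBM and -0.36, -0.47 and -0.68 in Drug, in order of replicate number. In Drug vs FM 1 of the 10 genes fell over all genes tested, and all 10 log2 fold changes were negative (median -0.77). None of the 10 passed in the other 2 comparisons. With this score as a covariate, chosen after seeing the data, the lipid absorption list had a median of 0.23, an adjusted p of 0.193 and 1 gene past the threshold.

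In fatty acid oxidation 8 of 33 genes rose, 25 did not pass, and 15 rose when adjusted over the list alone. The count of 8 was 0 without any one of FM replicates 1 and 2 and Drug replicate 3, 1 without Drug replicate 1, 4 without Drug replicate 2 or SBM replicate 3, 3 with the score of lysosome-rich enterocyte genes as a covariate and 14 with DESeq2. The list passed camera at 3.10e-07, with adjusted p = 0.590 under an estimated correlation. Its genes cpt1b, acox3, hadhb and acadvl rose 7.61-fold, 2.92-fold, 2.44-fold and 2.17-fold. In oxidative phosphorylation 7 of 70 genes rose, 43 when adjusted over the list alone, among them ndufb5 (1.72-fold), sdhb (1.69-fold), atp5f1b (1.60-fold) and sdhc (1.49-fold). That list passed camera at 1.24e-09, with adjusted p = 0.713 under an estimated correlation. Its count of 7 was 0 in both fits to FPKM and without any one of FM replicates 1 and 2, SBM replicate 3 and Drug replicates 1, 2 and 3, and 1 without FM replicate 3 and with the covariate. It was 2 without a filter and without FM replicate 3 and SBM replicate 2, 14 without SBM replicate 1 and 28 with DESeq2.

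Genes of glutathione metabolism included several large rises, although the list of 38 did not pass (adjusted p of 0.131). The peroxidase gpx4a went from 355 ± 163 to 2659 ± 422 CPM (log2 fold change 2.90, SE 0.52, adjusted p = 0.0270), mgst3b rose 5.89-fold, mgst3a 3.15-fold and gsr 2.10-fold. In this list 7 genes rose and none fell over all genes tested, 11 rose and 3 fell when adjusted over the list alone, and 18 of 38 log2 fold changes were negative (median 0.02). The count of 7 was 0 without FM replicate 2, 1 without Drug replicate 3, 2 without FM replicate 1 and with the score of lysosome-rich enterocyte genes as a covariate, 3 without Drug replicate 1 or 2 and 11 with DESeq2. Glutathione genes also fell without FM replicate 3 (1), SBM replicate 1 (2) or SBM replicate 2 (1) and with DESeq2 (3). Ion transporters slc26a6 and slc4a4a, which move anions and bicarbonate, rose 3.80-fold and 4.94-fold. Their list did not pass (adjusted p of 0.324), with 8 of 15 log2 fold changes negative, and 5 genes rose and 2 fell when adjusted over the list alone. The goblet cell gene agr2, the galectin lgals2b and the basement membrane and matrix collagens col4a1, col4a2 and col6a3 rose 1.99-fold, 1.80-fold, 1.54-fold, 1.63-fold and 1.62-fold, in lists that did not pass (adjusted p of 0.456, 0.360 and 0.339 for goblet cells, antimicrobial proteins and matrix). Neither these 5 genes nor the 2 transporters passed without FM replicate 1, FM replicate 2 or Drug replicate 3.

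Lower in Drug were several clock and immune genes. The clock genes bhlhe40, arntl1a, cry1b and arntl2 fell 2.32-fold, 1.98-fold, 1.72-fold and 1.60-fold. These were the 4 of 31 clock genes past the threshold, 9 fell when adjusted over the list alone, and the list passed camera downwards at 0.0162 (adjusted p = 0.713 with an estimated correlation). The clock count was 0 without any one of FM replicates 1 and 2 and Drug replicates 1 and 3, 1 without Drug replicate 2, 2 without FM replicate 3 or SBM replicate 3, 8 without SBM replicate 1, 7 on the 2 groups alone and 9 with DESeq2. Here too a difference in time of sampling cannot be told apart from the group. The cytokines csf3a and il17d fell 3.60-fold and 2.23-fold and the other 20 of the inflammatory list did not pass, with camera at 0.00475 and adjusted p = 0.590 under an estimated correlation. The B cell kinase btk fell 1.79-fold and the other 16 of its list did not pass (0.00221 by camera, and adjusted p = 0.713 with an estimated correlation). The intestinal identity factor cdx1a fell 2.25-fold. Its stem cell and Wnt/Notch list did not pass camera (adjusted p of 0.0558, under 0.05 in 13 of 20 alternatives) and passed fry at 0.0169. Neither cytokine passed without any one of FM replicates 1 and 2 and Drug replicates 1 and 3, and 1 inflammatory gene passed without SBM replicate 3. The calls of btk and cdx1a were lost without any one of FM replicates 1 and 2, SBM replicate 3 and Drug replicates 1, 2 and 3, and that of btk without FM replicate 3 too. Brush border and enteroendocrine lists passed upwards at 0.000551 and 0.00475, with no gene past the threshold and adjusted p = 0.666 and 0.748 under an estimated correlation. Brush border genes rose without FM replicate 3 (1 gene), SBM replicate 1 (2 genes) or SBM replicate 2 (5 genes, with 1 lower), enteroendocrine genes without SBM replicate 1 or 2 (3 genes each), and DESeq2 called 8 and 4 genes of these lists. With the score of lysosome-rich enterocyte genes as a covariate the adjusted p was 0.656 for brush border, 0.921 for enteroendocrine cells, 0.384 for B and plasma cells, 0.168 for inflammatory cytokines and 0.0866 for the clock list. The clock list was at 0.0870 without Drug replicate 1 and 0.131 without FM replicate 2, and enteroendocrine cells at 0.0715 without FM replicate 3. With the stricter filter enteroendocrine cells were at 0.109 and inflammatory cytokines at 0.117.

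Among the largest rises outside those lists were greb1, from 1.58 ± 0.261 to 40.6 ± 3.32 CPM (log2 fold change 4.68, SE 0.28, adjusted p = 0.000642), the creatine synthesis gene gatm (50.9-fold), zgc:136472 (26.4-fold), si:ch211-266i6.3 (22.8-fold) and the AMP deaminase ampd2b (21.7-fold). The aquaglyceroporin gene aqp10a had 433, 2383 and 1173 counts in Drug and 6, 0 and 3 counts in FM. Its fitted log2 fold change of 8.78 (SE 1.56, adjusted p = 0.0300) depends on the prior count. The largest falls were in si:ch211-117c9.2 (12.2-fold), cdab (8.94-fold), egln3, an oxygen-sensing prolyl hydroxylase, from 367 ± 58.3 to 43.0 ± 22.7 CPM, palm3 (5.43-fold), whrna (4.86-fold), pip5kl1 (3.66-fold) and stxbp6 (3.42-fold).

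**Figure D4:**
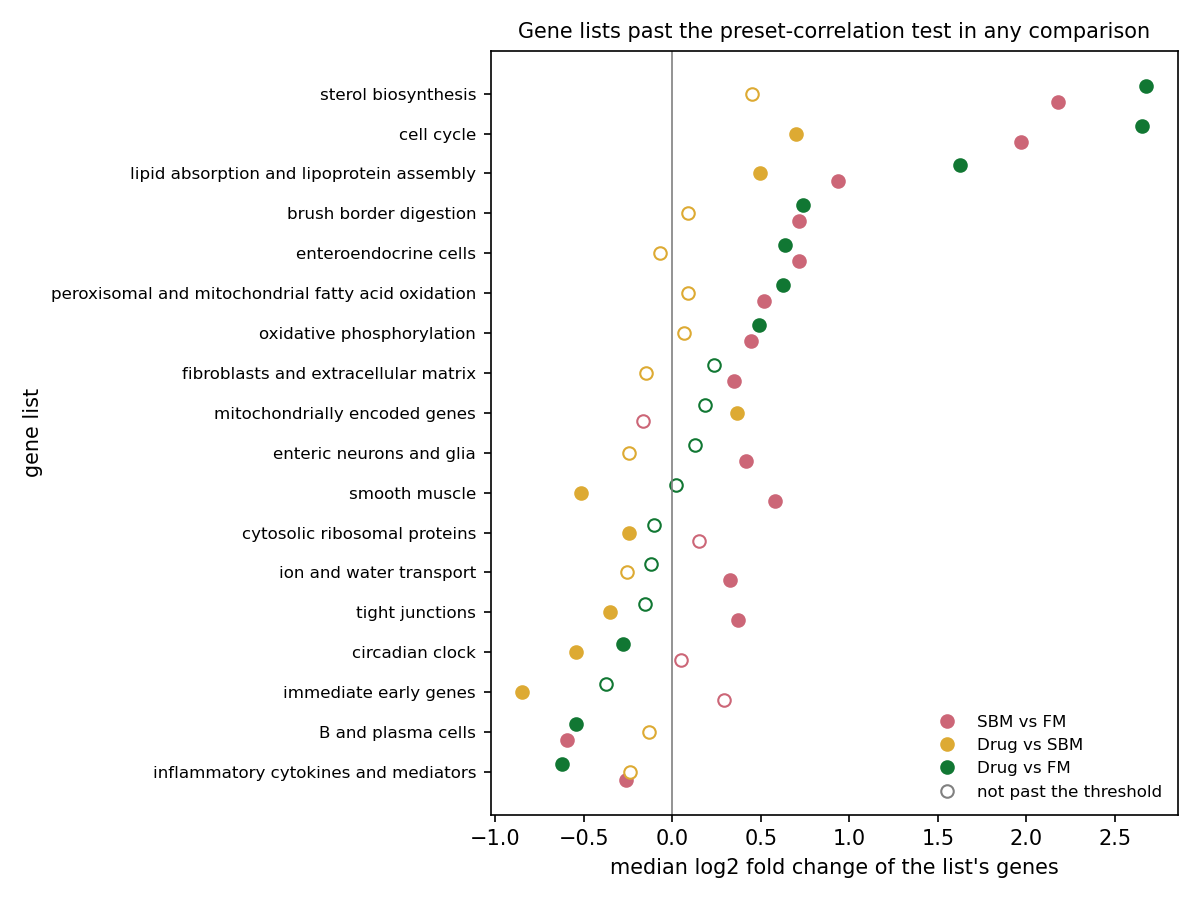
Median log2 fold change of the tested genes of each list that passed camera in any comparison, 1 point per comparison, filled where the list passed in that comparison, with the hepatocyte list left out. Sterol biosynthesis lies at 2.18 in SBM vs FM, 2.68 in Drug vs FM and 0.45 in Drug vs SBM.

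In Drug vs FM 777 of 17731 genes passed with edgeR, 507 higher and 270 lower, and 259 had only a LOC number. Of the 105 genes of SBM vs FM, 76 also passed here in the same direction. Independent lists would share 2.65 genes. Simulated unchanged groups with shared FM libraries gave 0.05 on average, an overlap set near 0 in advance, since no gene was given a change. The covariance of the log2 fold changes was 0.784 against 0.115 simulated (0.462 against 0.1025 without liver-restricted genes). Part of the excess may come from the shared FM libraries. DESeq2 called 2431 genes and the fit on the 2 groups alone 1578. The counts were 102, 247 and 44 without Drug replicates 1, 2 and 3, and 109, 10 and 568 without FM replicates 1, 2 and 3. They were 1711, 1211 and 281 without SBM replicates 1, 2 and 3, and 1199 without FM replicate 3 and SBM replicate 2 together. Of the 568 genes without FM replicate 3, 405 were among the 777. Separate handling of FM replicates 1 and 2, taken up below, cannot be told apart from the group in either comparison with FM.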

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

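Leaving out FM replicate 3 and SBM replicate 2, the lysosome-rich enterocyte score and the removal of liver-restricted genes were chosen after seeing the data, and the causes of the differences below were not tested unless stated. Counts within 1.5 times of the reported ones are not listed, although the genes behind a similar count can differ. In Drug vs FM 592 genes passed with the score, but only 224 of them were among the 777 reported. SBM vs FM had 105 genes, and 1597 with DESeq2, 237 with the stricter filter (9854 genes tested), 0 on the 2 groups alone (fewer libraries), 49 and 69 with limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), 330 without both libraries, 535 with the score and 169 without liver-restricted genes. Drug vs SBM had 7 genes, and 0 with upper-quartile factors, 614 with DESeq2, 0 on the 2 groups alone, 4 and 0 with limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), 0 without both libraries and 31 with the score. Drug vs FM had 777 genes, and 2431 with DESeq2, 1578 on the 2 groups alone and 1199 without both libraries. Genes that changed in opposite ways numbered 1, and 0 with upper-quartile factors, 150 with DESeq2, 2 with the stricter filter, 0 on the 2 groups alone, 0 and 0 with limma-trend, 0 without both libraries, 5 with the score and 2 without liver-restricted genes. With each library left out in turn the counts ranged from 2 to 424 in SBM vs FM, 0 to 36 in Drug vs SBM, 10 to 1711 in Drug vs FM, and 0 to 9 for opposite changes. Gene lists past the threshold ranged from 7 to 16, 6 to 11 and 9 to 15, in the same order. With an estimated correlation 0, 0 and 0 lists passed, against 15, 8 and 10 with the preset one, and fry gave 1, 1 and 1. Same-numbered libraries of different groups had deviations that correlated at 0.05 to 0.37, and differently numbered ones at -0.22 to 0.0047. All 9 libraries correlated best with their own number, a hint from the data that the numbers may pair them. A bound of 0.1 was passed in 7 of 9 pairs (in all 3 of FM with SBM) and not in all, so the reported fits were left unpaired. A pairing is not excluded by this. With the replicate block the counts were 295 genes in SBM vs FM, 1 in Drug vs SBM, with 0 of the 7 genes among them, and 1293 in Drug vs FM, and the 1 gene that changed in opposite ways was not yap1. With this block the sterol list in Drug vs SBM had an adjusted p of 0.00531, and 12 sterol genes passed in SBM vs FM, against 3 without it. Of the values of named genes under the alternatives, 354 of 582 in SBM vs FM, 214 of 293 in Drug vs SBM and 759 of 1087 in Drug vs FM kept their direction and side of the threshold. Of the rest 222, 67 and 328 lost the threshold, 6, 12 and 0 gained it, and 0 changed sign. In Drug vs SBM many of the kept values belong to genes that did not pass in the reported fit. The named genes that did pass kept the threshold in fewer alternatives: mknk2b in 9 of 21, hey1 in 6 of 20, osgn1 in 8 of 21, and yap1 and pnrc2 in 7 of 21 each. Genes of low count, such as aqp10a in FM, are limited by depth.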

Other observations

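The tests of the liver transcripts, the sterol tests without FM replicate 3 and against FM replicate 3 alone, the marker lists and the covariate were chosen after the result was seen. Clock genes are given as values only, since they were grouped after their values were seen. In SBM vs FM, 12 of 13 genes of per, nr1d, dbp, tef, hlf and ciart had positive log2 fold changes, with a median of 0.69, while 7 of 8 genes of arntl, clock, npas2, cry1, nfil3 and rorca had negative ones, with a median of -0.29. In Drug vs FM the same groups had medians of 0.16 (9 of 13 positive) and -0.82 (8 of 8 negative), and in Drug vs SBM -0.58 and -0.56. None of these genes passed over all genes tested in SBM vs FM or in Drug vs SBM, and 3 of the group of arntl fell in Drug vs FM. With no time of sampling in the labels, a difference in time of day between the groups could not be tested.

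Interferon response, antigen presentation, pattern recognition and goblet cell lists did not pass camera in any of the 3 comparisons. Pattern recognition and NF-kappaB signalling had an adjusted p of 0.0583 by camera in Drug vs FM and passed downwards in 4 of 20 alternatives. In Drug vs SBM the adjusted p was 0.467 for interferon response, 0.974 for antigen presentation, 0.359 for pattern recognition and NF-kappaB signalling, 0.738 for inflammatory cytokines and 0.898 for goblet cells and mucus, and for these lists none of the members passed over all genes tested in that comparison. The inflammatory cytokine list passed downwards in both comparisons with FM, with adjusted p = 0.752 in SBM vs FM and adjusted p = 0.590 in Drug vs FM with an estimated correlation.

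Liver transcripts in FM replicate 3 are the first pattern. An acute-phase response of the gut is argued against as the whole cause by 8 liver products that such a response lowers or leaves. Their median log2 ratio to FM replicates 1 and 2 was 10.23 (lowest 8.37). The 8 were picked after the pattern was seen, and 4 of them (ttr, fetub, tfa and itih2) are in the hepatocyte list itself. Outside that list, ahsg1, ahsg2, fabp10a and apoc4 were at 355 to 1654 CPM in FM replicate 3. In FM replicates 1 and 2 these genes were at 0.684 CPM or less. A liver sample under an intestine label is argued against by the brush border list, whose median log2 ratio was 0.11 over 17 genes. Liver tissue or liver RNA in this library stays open: 93.8% of the hepatocyte list stood over 10-fold above every other library, which restates the pattern with a bound set after it was seen and so decides nothing for it. Of that list, 2 of 16 genes were at 1 CPM or more in all other 8 libraries and 1, c9, is also in another fixed list, and no biological explanation from the groups was tested.

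The sterol list, which lay higher in SBM than in FM with 3 of 25 genes past the threshold, is the second pattern. A difference in the lysosome-rich enterocyte score is argued against as the whole cause. With the score as a covariate the list's median was 1.74 (quartiles 1.15 to 2.23, and 2.18 without it), and all 25 members stayed above 0. A difference in gut segment stays open, since the score genes differed little between SBM and FM (median log2 fold change -0.20). All 10 proximal absorptive genes had positive log2 fold changes (median 2.37, 0 past the threshold) and were not used as a covariate. Their median log2(CPM + 1) was 9.51, 5.64 and 8.90 in SBM and 6.55, 5.34 and 7.02 in FM, in order of replicate number. Liver RNA in FM replicate 3 is argued against, since the median without that library was 2.20. Separate handling of FM replicates 1 and 2 cannot be told apart from the group: hpxb was at 3.82 to 7.03 CPM in the 6 SBM and Drug libraries and at 0.246 and 0.0264 CPM in these, and the median of SBM over FM replicate 3 alone was 1.89, from 1 library only. The diet that the group names may point to stays open and untested.

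The lipid absorption list, which lay higher in Drug than in FM with 5 of 21 genes past the threshold, is the third pattern. Liver RNA in FM replicate 3 is argued against, with a median of 1.71 without that library against 1.63 with it. Separate handling of FM replicates 1 and 2 cannot be told apart from the group here either. In Drug hpxb was at 4.83 to 6.55 CPM, against 0.246 and 0.0264 CPM in these 2 FM libraries. A difference in gut segment or in the share of lysosome-rich enterocytes cannot be told apart from the group, since the Drug scores, -0.36, -0.47 and -0.68, do not overlap the 0.26 to 0.50 of FM. With the score as a covariate the median was 0.23 (median SE of a gene 0.46, against 1.63 and 0.43 before), an estimate that rests on the SBM libraries, whose scores were -0.68, 0.77 and 0.16. SBM replicate 2 also had a proximal absorptive median of 5.64 against 5.34 to 7.02 in FM and 9.03 to 9.59 in Drug on the log2(CPM + 1) scale. All 10 score genes were at 1 CPM or more in every other library, all 10 proximal genes are also in fixed lists, and an effect of the Drug treatment on these cells stays open and untested.

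With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In SBM vs FM the real split gave 105 genes (1 of 10 splits with as many) and the highest other 0. In Drug vs SBM it gave 7 genes (1 of 10) and the highest other 0, and in Drug vs FM it gave 777 (1 of 10) and the highest other 0. For gene lists the real splits gave 15, 8 and 10, the highest others gave 18, 15 and 18, and 5, 9 and 6 of the 10 splits gave as many. Of 100 drawn splits of the 9 libraries, 2, the real one included, had 1 or more genes that changed in opposite ways in the SBM comparisons, a share under 0.05. The count is 1 gene and the highest other split had 60, so no claim of a reversal rests on it. That split kept the 3 FM libraries together against mixed SBM and Drug libraries, so its structure follows the difference of FM from the rest.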
